A study of Homo sapiens with 6 samples.

How the data were processed

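RNA of 6 HUVEC cultures, 3 per arm, was measured on Affymetrix Human Gene ST arrays, per the series' design text. Each column of the deposited table is 1 array with 33297 transcript clusters. Per the submitters' processing notes, the authors made the values with RMA, which corrects background, equalises probe distributions between arrays and summarises probes per transcript cluster. Its version and the annotation used are not given in the sources used here. The deposited values are taken as log2 expression because they lie between 1.52 and 15.12 in all arrays, and no step of gene centring is visible in them. Scanner files were not used here, so the scale and any later centring could not be set against scanner values and stay inferred. The column medians were 6.79, 6.79 and 6.75 for control replicates 1, 2 and 3 and 6.79, 6.77 and 6.72 for antisense replicates 1, 2 and 3. RMA makes arrays comparable under the assumption that most transcripts do not change, so a change shared by most genes would be removed.

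Clusters were named through the platform annotation, with symbols updated by gene identifier to the RefSeq gene table of assembly GRCh38.p14. Of the clusters, 19460 had 1 gene symbol, 1754 had several and 12083 are unnamed in that annotation, and 19429 of the first kind matched the gene table. No gene was named from a cluster with several symbols. The 19460 clusters stand for 18417 genes, of which 769 had more than 1 cluster and 210 of these had clusters that differed in sign. The cluster with the highest mean over the 6 arrays represented each gene. Genes with a mean above the 25th percentile of all clusters (5.35 log2 units) were tested, which left 15546. The build behind the array annotation is not given in the sources used here, so no coordinates are printed and the gene table served for names, chromosomes and neighbouring genes.

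The 2 arms were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided), and p was adjusted by Benjamini-Hochberg over the genes tested, with 0.05 as the threshold. Differences are antisense minus control. The fit without the replicate number was set as the main one before the data were examined, since the series states no pairing, and the fit with the number as a block was set as its alternative. Whether the numbers pair the arrays was decided before the calls of the fits were compared. Deviations from the arm means correlated across genes by 0.488, 0.526 and 0.522 between arrays of the same number. Every same-numbered pair thus lay above the preset limit of 0.1, and both fits are given. Arrays of different numbers correlated by −0.387 to −0.213. Deviations cancel out within an arm, so these negative values follow from the positive ones and add no evidence of pairing. The replicates are described as biological, but whether a number marks a shared isolate or day is not given in the sources used here.

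Before the data were examined, 27 gene lists were fixed, including markers of 4 other cell types, and tested with camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera asks whether a list moved against the other genes. With the correlation estimated for each list, 0 of the 11 lists that passed still did, and 0 of the 13 that passed with pairing. Fry, which asks whether the members move one way on balance, passed 1 list in each fit. The genes named were also fixed by a rule: EGFL7 and the targets taken up by the study, then per direction the 12 largest changes among genes that passed with arms that did not overlap or, where fewer than 5 passed, the 8 such genes with the smallest p, then up to 4 members of each list. Fewer than 5 genes passed in each direction without pairing, so the 8 with the smallest p were taken. Other list members were named after their values were seen: ADAMTS1, MMP14, CD34, PROCR, POSTN, FBN2, BMP4, LTBP1, CXCL2, AQP1, CYP1A1 and COL1A2, which passed in the paired fit, and AURKB, NDC80 and UBE2C, which did not.

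Both fits were tested on simulated data for the 15546 genes. Without pairing, 26.2% of genes changed by 0.5 on the log2 scale, 96.2% of those changed by 1 and 100% of those changed by 2 were recovered, with 0 unchanged genes called. With pairing the shares were 97.5%, 100% and 100%, with 17 unchanged genes called. The simulated noise was normal with the variances of the paired fit, already drawn toward their common value, so these shares may be too high. This noise was independent between genes. With pairing, a shifted list of 37 genes had a camera p of 2.33e-43 at the preset correlation and 0.00381 at the estimated one. The estimated form thus gave a much weaker result there without correlated members. The alternatives were other filters on dim probes, a further quantile normalization, median centring, cyclic loess, a trended and robust variance prior and array weights. Further ones were the mean of a gene's clusters, all clusters above the same 25th percentile, other thresholds, other set tests and leaving out each array. The same alternatives in the paired fit were added after seeing the data. A search for miR-126 seed sites in 3-prime untranslated regions had been planned and was not run, since no genome sequence was used here. Genes whose level could reveal a donor's sex are not reported. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.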

Results

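Human umbilical vein endothelial cells (HUVEC), primary cells taken from the vein of the umbilical cord, were given a morpholino directed against the primary transcript of miR-126 or a non-targeting control morpholino. Morpholinos are synthetic antisense oligomers that bind RNA without cutting it. The one used here is meant to hinder the steps that turn the miR-126 primary transcript into the microRNA, which is abundant in endothelium. The amount was 15 nmol in both arms, and total RNA was collected after 72 h. Each arm held 3 arrays, numbered 1 to 3, which the series describes as biological replicates. The 33297 transcript clusters of each array had a median between 6.72 and 6.79 log2 units, and 15546 genes entered the test. The number of arrays limits the precision of every value.

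The comparison of the antisense arm with the control arm asked which mRNAs differ when processing of the miR-126 primary transcript is targeted. The targeted locus gave the largest difference among the 15546 genes. MIR126, the gene of the targeted microRNA, rose from 5.94 ± 0.14 log2 units in control cells to 11.90 ± 0.50 in antisense cells (mean ± SD, n = 3 per arm). This is a 62.5-fold higher value, which background signal in the control arrays could understate. EGFL7, the endothelial gene within which MIR126 lies on chromosome 9, rose from 9.03 ± 0.03 to 10.50 ± 0.34, or 2.78-fold. GJA5, which encodes the gap junction protein connexin 40 of arterial endothelium and lies on chromosome 1, rose from 5.94 ± 0.06 to 7.26 ± 0.09, a difference of 1.32.

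Array by array, MIR126 read 6.10, 5.84 and 5.87 in control replicates 1, 2 and 3 and 12.27, 11.33 and 12.11 in antisense replicates 1, 2 and 3. EGFL7 read 9.06, 9.01 and 9.01 in the control replicates and 10.78, 10.12 and 10.61 in the antisense replicates. Whether the MIR126 cluster reads the primary transcript, the precursor or the mature microRNA was not analysed here, so its rise does not measure the amount of mature miR-126. In limma with Benjamini-Hochberg adjustment, the change was 5.97 (SE 0.21, adjusted p = 3.48e-06) for MIR126, 1.32 (SE 0.09, adjusted p = 0.000441) for GJA5 and 1.47 (SE 0.15, adjusted p = 0.0165) for EGFL7. All 3 genes were higher with antisense in 3 of 3 replicate numbers. EGFL7 no longer passed in limma without control replicate 1, 2 or 3 or antisense replicate 3 (adjusted p = 0.0577, 0.0570, 0.108 and 0.191). It also did not pass with all transcript clusters above the 25th percentile tested, named or not (limma adjusted p = 0.128). Its limma adjusted p ranged from 0.000597 to 0.191 across its alternatives, while its change stayed between 1.34 and 1.67.

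**Figure D1:**
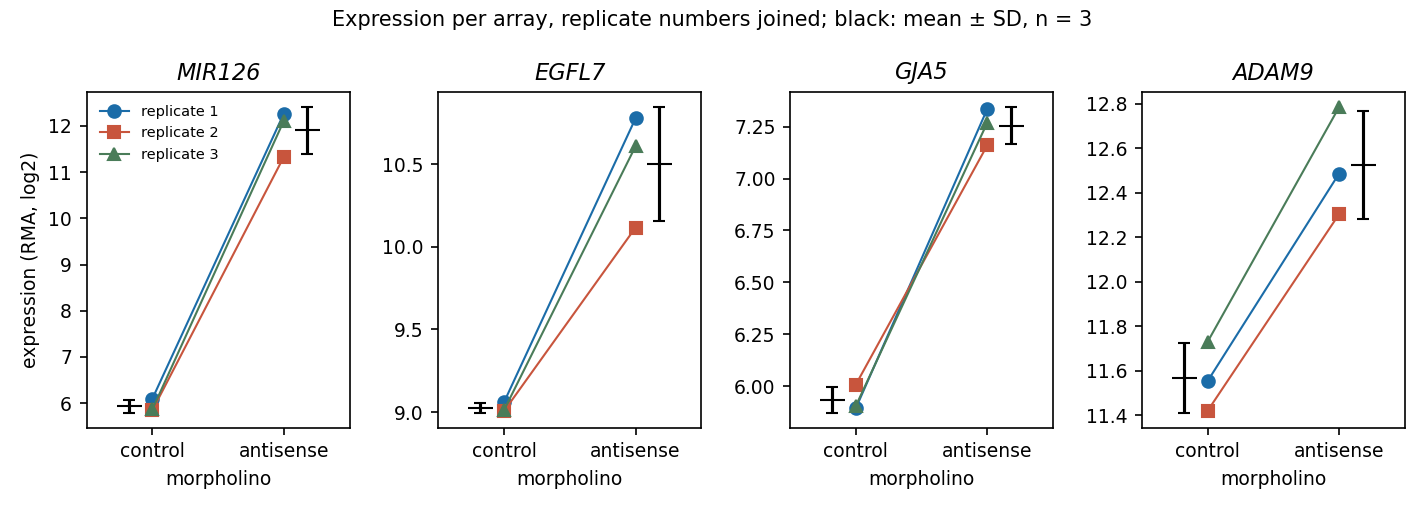
Expression of MIR126, EGFL7, GJA5 and ADAM9 on each array in log2 units (vertical axes, which differ between panels and do not start at 0), with lines joining arrays of the same replicate number and black bars giving mean ± SD, n = 3 per arm. Each gene was higher with the antisense morpholino in 3 of 3 replicate numbers, by 5.97, 1.47, 1.32 and 0.96 on average.

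MIR126, EGFL7 and GJA5 were the 3 genes that rose in the fit without pairing, and 0 genes fell (limma, adjusted p under 0.05), against 686 higher and 514 lower genes at an unadjusted p under 0.05. Arrays of the same replicate number shared deviations from their arm's mean, and with the replicate number as a block, called the paired fit from here on, 312 genes rose and 224 fell. All 536 of these went the same way in the 3 pairs, which is nearly fixed by selecting them on these same differences. Of these genes, 75 rose and 34 fell by at least 1.5-fold. The arms did not overlap for 1863 genes, which is 11.98% of those tested where chance gives 10% for exchangeable arrays and less for arrays that share deviations in pairs. The paired count was 57 without replicate 1, 489 without replicate 2 and 164 without replicate 3. It was 1 with all transcript clusters above the 25th percentile tested, named or not. With no filter on dim probes it was 156, with a stricter one 826 and with a trended, robust variance prior 991.

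Next to MIR126, EGFL7 and GJA5, the genes with the smallest p and with arms that did not overlap passed in the paired fit alone. Among those higher with antisense, ADAM9, a membrane-bound metalloprotease, rose in the paired fit by 0.96 (limma adjusted p = 0.104 without pairing and 0.00236 with it). EVI2B rose by 0.82, NOSTRIN, which binds endothelial nitric oxide synthase, by 0.77, the arterial ligand EFNB2 by 0.63 and LZTS1-AS1 by 0.57. Among those lower, the protease inhibitor SERPINE2 fell by 1.09 on the log2 scale (limma adjusted p = 0.220 without pairing and 0.00570 with it). GALNT15 fell by 1.07 on the log2 scale, MTMR10 by 0.81, the matricellular gene CCN1 by 0.65, KIFAP3 by 0.57, CAVIN4 by 0.56, CARD16 by 0.54 and MRPS33 by 0.45. Of 62 genes named by the fixed rule that passed in the paired fit, 18 passed without replicate 1, 56 without replicate 2 and 37 without replicate 3. The 16 that passed without each in turn were MIR126, EGFL7, GJA5, ADAM9, EVI2B, NOSTRIN, LZTS1-AS1, CCN1, SERPINE2, MTMR10, CARD16, PRIM1, H3C12, H1-3, ETV1 and RGS5.

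Of the miR-126 targets recalled as taken up by the study, SPRED1, an inhibitor of Ras and ERK signalling, went from 7.73 ± 0.11 to 8.04 ± 0.22 log2 units and the laminin receptor subunit ITGA6 from 10.89 ± 0.11 to 11.15 ± 0.12 (n = 3). Their differences in the paired fit were 0.31 (95% interval 0.15 to 0.48, limma adjusted p = 0.0557) and 0.26 (0.10 to 0.41, limma adjusted p = 0.0900). The adhesion molecule VCAM1 differed by −0.03 (−0.24 to 0.19) and RGS3 by −0.02 (−0.18 to 0.13). Over all genes 0 of these 4 passed in either fit, and adjusted over the list alone 0 passed without pairing and 2, SPRED1 and ITGA6, with it. The study may have chosen these genes on the same arrays, so the list is not independent evidence of its direction. The list did not pass as a set (camera adjusted p = 0.164, and adjusted p = 0.599 with an estimated correlation) except without antisense replicate 2 (camera adjusted p = 0.0265), and PIK3R2 and CRK were not analysed here.

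Among 30 measured targets named in other studies, ADAM9, the amino acid transporter SLC7A5 (0.47) and the histone methyltransferase EZH2 (0.38) rose in the paired fit, the vasoactive peptide ADM fell by 0.36 on the log2 scale, and 26 did not pass. Adjusted over the list alone, 2 rose and 1 fell without pairing and 4 rose and 1 fell with it. The median of the list was 0.08, with 22 members above 0 (camera adjusted p = 0.0130, and adjusted p = 0.459 with an estimated correlation). Its members moved upward on balance by fry (adjusted p = 0.0204), a call that ended with pairing (adjusted p = 0.0781). Calls among these targets were 1 higher and 0 lower without replicate 1, 4 and 1 without replicate 2, 1 and 0 without replicate 3, and 2 and 0 with no filter on dim probes.

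Mitotic (G2/M) genes were higher as a list (camera adjusted p = 4.68e-24, and adjusted p = 0.467 with an estimated correlation). All 37 measured had values above 0, with a median of 0.63 (0.41 without control replicate 1), and 34 of them rose in the paired fit while 0 passed without pairing. CDC20, an activator of the anaphase-promoting complex, went from 9.12 ± 0.22 to 9.84 ± 0.34 log2 units and the cytokinesis scaffold ANLN from 8.90 ± 0.44 to 9.63 ± 0.29 (n = 3), and both rose in the paired fit, as did PTTG1 (0.66) and ECT2 (0.48). The medians of the list within replicate numbers 1, 2 and 3 were 0.67, 0.34 and 0.85. AURKB (0.33), NDC80 (0.46) and UBE2C (0.45), named here after their values were seen, did not pass. Adjusted over the list alone, 32 genes rose without pairing and 37 with it. In the paired fit over all genes, 3 rose without replicate 1, 37 without replicate 2, 16 without replicate 3 and 13 with no filter on dim probes.

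Of 36 measured genes of DNA replication and the G1/S transition, 11 rose in the paired fit, among them the primase subunit PRIM1 (0.61), the ubiquitin ligase subunit DTL (0.62) and the replication factors GINS1 (0.54) and CDC45 (0.48), and 25 did not pass. The list had a median of 0.27, and 0.41 without antisense replicate 1 (camera adjusted p = 8.11e-13, and adjusted p = 0.467 with an estimated correlation). Adjusted over the list alone, 1 gene rose without pairing and 25 with it. Of 28 replication-dependent histone genes, 16 rose in the paired fit, including H3C12 (0.78), the linker histone H1-3 (0.68), H2BC13 (0.54) and H2BC9 (0.45). Their median was 0.41, and 0.25 without control replicate 1 (camera adjusted p = 7.09e-14, and adjusted p = 0.467 with an estimated correlation), with 3 higher without pairing and 24 with it adjusted over the list alone. Histone genes are near-identical copies, so the assignment of a signal to 1 of them is uncertain. Without replicate 1, 2 or 3 the paired fit called 1, 11 or 3 of the replication genes and 3, 15 or 5 of the histones, and with no filter on dim probes 4 and 8. With the stricter filter or the trended prior it called 17 or 19 of the replication genes.

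Targets of p53 were slightly lower as a list. Of 27 measured, 22 had values below 0 and the median was −0.09 (camera adjusted p = 0.000523, and adjusted p = 0.494 with an estimated correlation). Leaving out 1 array moved it to −0.15 without control replicate 1, −0.05 without antisense replicate 1 or control replicate 3 and −0.16 without antisense replicate 3. SPATA18, a mitochondrial quality control gene, fell by 0.39 on the log2 scale in the paired fit, and GDF15 (−0.36), SESN1 (−0.24) and PLK2 (−0.21) did not pass. Adjusted over the list alone, 0 passed without pairing and 1 with it. The paired fit called 0 of them lower without replicate 1 or replicate 3 or with no filter, and 2 without replicate 2, with the stricter filter or with the trended prior.

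**Figure D2:**
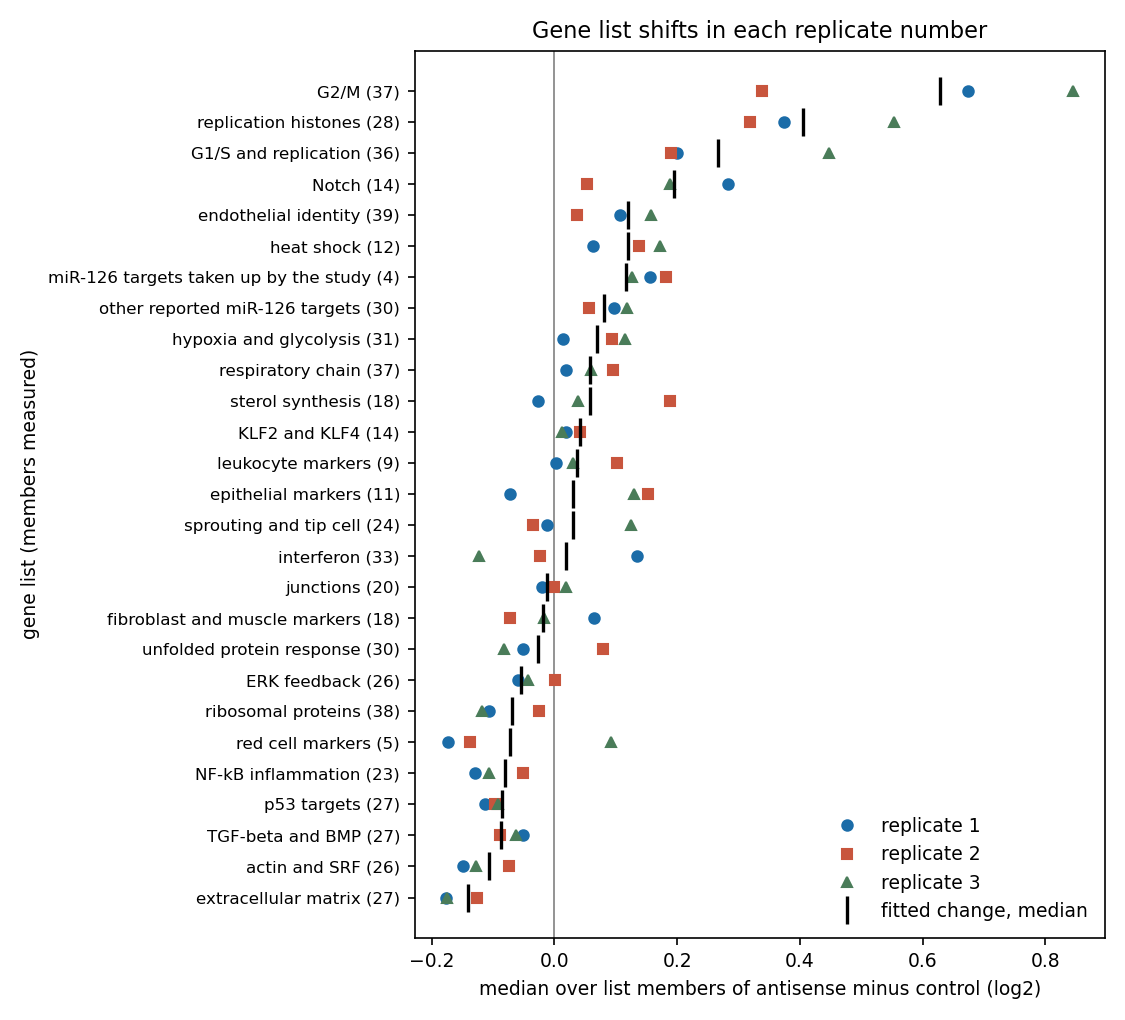
Median over the measured members of each fixed gene list of antisense minus control in log2 units (horizontal axis), within replicate numbers 1, 2 and 3 (points) and over the fitted changes (black ticks), with the number of members measured in brackets. The G2/M list lies at 0.67, 0.34 and 0.85 in the 3 replicate numbers and the extracellular matrix list at −0.18, −0.13 and −0.18.

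Genes of the Notch pathway, which sets arterial identity and restrains sprouting, were higher as a list (median 0.19, camera adjusted p = 0.00101, and adjusted p = 0.467 with an estimated correlation). Of 14 measured, GJA5, EFNB2 and the Notch ligand DLL4 (0.61) rose in the paired fit, the ligand JAG1 fell by 0.53 on the log2 scale, and 10 did not pass. GJA5 alone rose without pairing. The median was 0.12 without antisense replicate 1 and, with pairing, 0.13 without replicate 1. Of these genes, 3 rose and 1 fell without pairing and 7 rose and 2 fell with it adjusted over the list alone. Without replicate 1, 2 or 3 the paired fit called 1, 4 or 2 of these genes higher and 0, 1 or 1 lower.

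Of 39 measured endothelial marker genes, 4 rose in the paired fit: EGFL7, the diaphragm protein PLVAP (0.55), the nitric oxide synthase NOS3 (0.40) and PROCR (0.32). The lymphatic transcription factor PROX1 fell by 0.45 on the log2 scale and CD34 by 0.54, and 33 genes did not pass. EGFL7 alone rose without pairing, and as the gene within which MIR126 lies it belongs to the targeted locus. The list was not tested without EGFL7. The median was 0.12 (camera adjusted p = 0.00393, and adjusted p = 0.467 with an estimated correlation), and 4 rose and 1 fell without pairing and 8 rose and 6 fell with it adjusted over the list alone. The set did not pass without antisense replicate 1 (camera adjusted p = 0.0610, over a range of 0.000337 to 0.467 across its alternatives) or, with pairing, without replicate 1 (0.0802) or 3 (0.0602, median 0.07). Without replicate 1, 2 or 3 the paired fit called 1, 4 or 2 of the markers higher and 1, 2 or 2 lower, with no filter 2 and 2, and with the trended prior 6 and 6.

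Sprouting and tip cell genes went both ways. Of 24 measured, DLL4, the metalloproteases ADAMTS1 (0.56), ADAMTS9 (0.45) and MMP14 (0.32) rose in the paired fit, and the growth factor PDGFB, the peptide APLN and the TEK ligand ANGPT2 fell by 0.56, 0.56 and 0.55 on the log2 scale. The list did not pass as a set (camera adjusted p = 0.763, and adjusted p = 0.918 with an estimated correlation), and 3 rose and 2 fell without pairing and 5 rose and 7 fell with it adjusted over the list alone. Without replicate 1, 2 or 3 the paired fit called 0, 4 or 1 of them higher and 0, 4 or 2 lower, and 1 and 2 with no filter. The stricter filter and the trended prior each gave 5 and 6. Of 20 junction genes, JAM3 rose by 0.54 and ANGPT2 fell in the paired fit, and the list did not pass (camera adjusted p = 0.429, median −0.01 with a mean of 0.03). Of 14 genes that depend on KLF2 and KLF4, the transcription factors induced by blood flow, 8 had values above 0 and 6 below. In the paired fit NQO1 (0.60), CYP1A1 (0.42), NOS3 and AQP1 (0.39) rose. HMOX1 (−0.36, limma adjusted p = 0.0501 in the paired fit) did not pass, and neither did the list (camera adjusted p = 0.597). When adjusted over the list alone, 1 junction gene and 2 KLF genes rose without pairing, and 2 and 4 rose and 1 and 3 fell with it. With replicate 1, 2 or 3 left out, the paired fit called 0, 2 or 1 junction genes and 0, 2 or 1 KLF genes higher, and 0, 1 or 0 and 0, 2 or 0 lower. With no filter it called 1 gene of each list higher and 0 lower, and with the trended prior 3 and 4 higher and 1 and 2 lower.

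Genes of the extracellular matrix were lower as a list (camera adjusted p = 4.80e-06, and adjusted p = 0.467 with an estimated correlation). Of 27 measured, 22 had values below 0 with a median of −0.14, and 4 fell in the paired fit. The proteoglycan BGN went from 11.40 ± 0.47 to 10.65 ± 0.47 log2 units (n = 3) and fell by 0.75 on the log2 scale, POSTN by 0.55, FBN2 by 0.41 and the laminin subunit LAMA4 by 0.32. The calcification inhibitor MGP (−0.75, limma adjusted p = 0.0519 in the paired fit) and COL5A1 (−0.24) did not pass. By adjustment over the list alone, 1 gene fell without pairing and 12 fell and 1 rose with it. With replicate 1, 2 or 3 left out, the paired fit called 1, 3 or 1 of them lower, and 0, 8 or 10 with no filter on dim probes, the stricter filter or the trended prior.

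Of 26 genes of the actin cytoskeleton and the transcription factor SRF, CCN1, ANKRD1 and CCN2 fell in the paired fit, by 0.65, 0.48 and 0.41 on the log2 scale. These 3 are induced by stretch and by SRF or YAP and do not encode cytoskeletal proteins, while the muscle actin ACTA2 (−0.30) and the myosin light chain MYL9 (−0.26) did not pass. The median was −0.11 (camera adjusted p = 2.50e-05, and adjusted p = 0.467 with an estimated correlation), with 2 lower without pairing and 8 with it adjusted over the list alone. Of 27 genes of TGF-beta and BMP signalling, CCN1, CCN2, BMP4 (−0.61) and LTBP1 (−0.44) fell and the receptor TGFBR1 (0.60) rose in the paired fit. That list passed by camera with pairing (adjusted p = 0.0157) and not without it (adjusted p = 0.0632), at adjusted p = 0.448 with an estimated correlation in the paired fit, and its members moved downward on balance by fry with pairing (adjusted p = 0.0198). Without pairing it passed when control replicate 1 (camera adjusted p = 0.0297), control replicate 2 (0.00612) or antisense replicate 3 (0.0106, median −0.18) was left out. Its median of −0.09 was −0.05, −0.04 and −0.02 without antisense replicates 1 and 2 and control replicate 3, −0.05 with pairing without replicate 2 and −0.15 with the stricter filter. When adjusted over the list alone, 1 rose and 1 fell without pairing and 5 rose and 8 fell with it. With replicate 1, 2 or 3 left out, the paired fit called 1, 4 or 2 of the actin and SRF genes and 1, 4 or 1 of the TGF-beta and BMP genes lower, and 0, 1 or 1 of the latter higher. With no filter, the stricter filter or the trended prior it called 3, 8 or 8 of the former and 2, 7 or 7 of the latter lower. Under these settings 1, 3 or 3 of the TGF-beta and BMP genes were higher. Of 26 ERK output and feedback genes, ETV1 rose by 0.74 and SPRY2 fell by 0.68 on the log2 scale in the paired fit, EPHA2 (−0.30) and EGR1 (−0.33) did not pass, and neither did the list (camera adjusted p = 0.299). When adjusted over the list alone, 1 of them rose without pairing, and 2 rose and 2 fell with it. In the paired fit SPRY2 did not pass without replicate 1, or with no filter. Without replicate 2 or with quantile normalization, 2 of these genes were lower and 1 higher. The stricter filter and the trended prior each gave 2 lower and 2 higher, and median centring 1 lower and 2 higher.

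**Figure D3:**
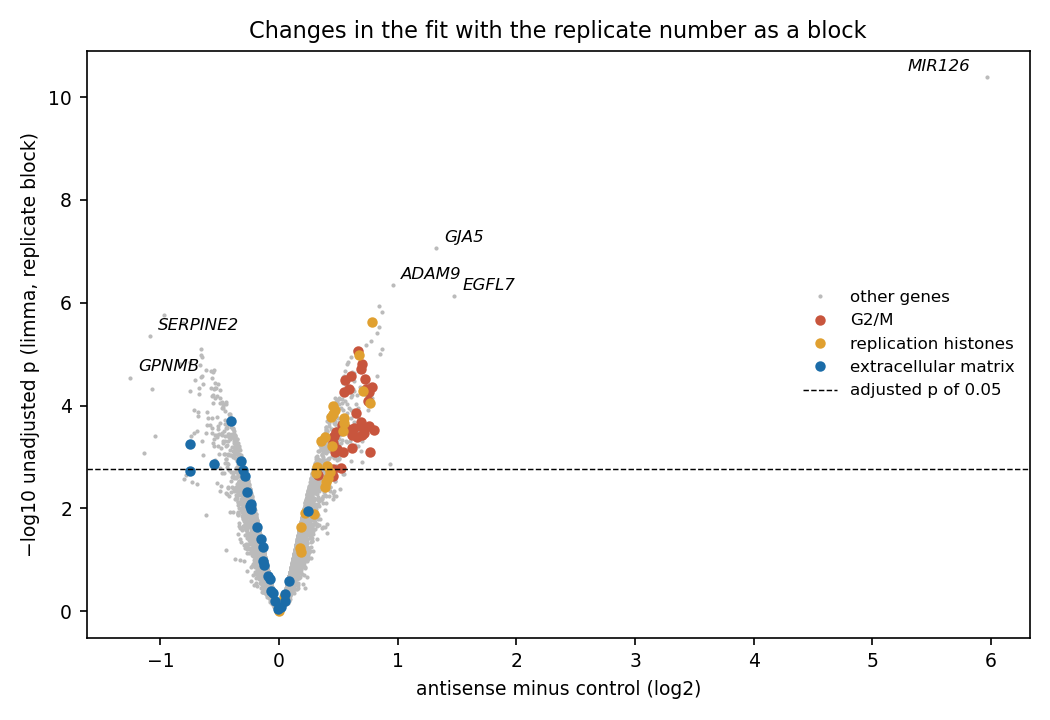
Change of each tested gene (antisense minus control, log2, horizontal axis) against −log10 of its unadjusted p in the paired limma fit (vertical axis), with the G2/M, histone and extracellular matrix lists coloured and a dashed line at an adjusted p of 0.05. In this fit 312 genes rose and 224 fell, and 34 of the 37 G2/M genes lie above the line on the right.

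Of 23 measured inflammatory genes that depend on NF-kB, CXCL2 fell by 0.35 on the log2 scale in the paired fit, and NFKBIZ (−0.30), PTGS2 (−0.39), CXCL8 (−0.31) and LIF (0.19) did not pass. The median was −0.08, −0.23 with the stricter filter and −0.12 with array weights or, with pairing, without replicate 2. The list passed by camera with pairing (adjusted p = 0.00583, and adjusted p = 0.448 with an estimated correlation) and not without it (adjusted p = 0.104). Of 33 interferon response genes, IFIT2, IFIH1 and SAMD9L fell in the paired fit by 0.61, 0.46 and 0.46 on the log2 scale and IFITM1 rose by 0.53, while the list had a median of 0.02 and a mean of −0.04 and did not pass (camera adjusted p = 0.405). When adjusted over the list alone, 0 NF-kB genes passed without pairing and 3 rose and 9 fell with it, and 1 interferon gene rose and 1 fell without pairing and 3 rose and 6 fell with it. With replicate 1, 2 or 3 left out, the paired fit called 0, 4 or 0 of the NF-kB genes lower and 2, 1 or 0 of the interferon genes lower, and 0, 1 or 1 of the latter higher. With no filter it called 0 genes of both lists and with cyclic loess 0 NF-kB genes. The stricter filter and the trended prior each gave 6 lower NF-kB genes. They each gave 3 higher interferon genes, beside 3 lower ones with the stricter filter and 4 with the trended prior. The interferon list passed with pairing without replicate 1 (camera adjusted p = 0.00181, median −0.06). Without pairing, leaving out antisense replicate 1 or control replicate 2 let the NF-kB list (camera adjusted p = 0.0211 and 0.000967, medians −0.16 and −0.17) and the interferon list (0.00461 and 0.0127, medians −0.08 and −0.09) pass as lower. The NF-kB median was −0.02 without control replicate 1 or antisense replicate 2 and −0.21 without antisense replicate 3.

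Among stress and metabolic lists, 12 heat shock genes were higher as a set (median 0.12, camera adjusted p = 0.0114, and adjusted p = 0.599 with an estimated correlation), with HSPB1 (0.30) higher in the paired fit and HSP90AA1 (0.30) not passing. That set did not pass without control replicate 1 (camera adjusted p = 0.127, median 0.06), antisense replicate 2 (0.141, median 0.07) or antisense replicate 3 (0.0980, median 0.07; it was 0.19 without antisense replicate 1), over a range of 0.000188 to 0.599 across its alternatives, or with pairing without replicate 2 (0.0606). The serine synthesis enzyme PHGDH (0.63) and the cystine transporter SLC7A11 (0.50) rose among 30 genes of the unfolded protein response. The glycolytic enzymes LDHA (0.40) and TPI1 (0.37) rose among 31 hypoxia and glycolysis genes while ADM fell. These are calls of the paired fit. Neither list passed (camera adjusted p = 0.763 and 0.285), nor did 18 sterol synthesis genes (0.104) or 37 respiratory chain genes (0.264), where 0 genes passed in either fit. The sterol synthesis list passed with pairing without replicate 1 (camera adjusted p = 0.0241, median 0.11). Without pairing it passed when control replicate 1 (camera adjusted p = 0.0155), antisense replicate 2 (0.0305) or control replicate 3 (0.00669) was left out. So did the hypoxia list without antisense replicate 1 (0.0497) or control replicate 3 (0.0343) and the respiratory chain list without control replicate 3 (0.0343). Cytosolic ribosomal protein genes were lower as a set, with 35 of 38 below 0 and a median of −0.07, and −0.11 with pairing without replicate 2 (camera adjusted p = 5.15e-06, and adjusted p = 0.459 with an estimated correlation), though 0 of them passed in either fit over all genes or adjusted over the list alone. When adjusted over the list alone with pairing, 3 heat shock and 3 unfolded protein genes rose, 3 hypoxia genes rose and 1 fell, and without pairing 0 passed in each of these lists. Without replicate 1 or 3 the paired fit called 0 genes of the heat shock, unfolded protein and hypoxia lists, and without replicate 2 it called 0, 2 and 1 higher and 1 of the hypoxia genes lower. With no filter it called 0 genes of these lists, and with the trended prior 2, 4 and 5 higher and 1 of the hypoxia genes and 5 of the ribosomal protein genes lower.

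Markers of other cells a cord vein culture could hold did not pass as sets in either fit. The camera adjusted p was 0.972 for 18 fibroblast and smooth muscle markers, 0.210 for 9 leukocyte markers, 0.597 for 5 red cell markers and 0.291 for 11 epithelial markers, with medians of −0.02, 0.04, −0.07 and 0.03. In the paired fit the pericyte gene RGS5 rose by 0.63 and COL1A2 fell by 0.47 on the log2 scale, both with a wide spread between control replicates (SD 0.67 and 0.70). The leukocyte gene LAPTM5 and the epithelial keratin KRT19 each rose by 0.55 in the paired fit. The epithelial gene EPCAM was lower by 0.48 and did not pass in that fit (limma adjusted p = 0.0551). Of the 11 epithelial markers, 8 had values above 0 and 3 below. The leukocyte list passed without antisense replicate 3 (camera adjusted p = 0.0159). The epithelial list passed with the filter on dim probes at the 50th percentile (camera adjusted p = 0.0290 without pairing and 0.0439 with it). When adjusted over the list alone, 1 leukocyte and 1 epithelial marker rose without pairing, and with it 2 fibroblast markers rose and 2 fell, 1 leukocyte marker rose, and 2 epithelial markers rose and 1 fell. COL1A2 and KRT19 did not pass with pairing without replicate 1 or replicate 3, and LAPTM5 did not pass without replicate 1.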

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

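Alternatives in the paired fit were chosen after seeing the data; all others were planned. Without pairing, MIR126 and GJA5 kept their direction and their call in each alternative in which they were tested, and the count of 3 genes stayed within 2 to 4 except with array weights (5) and with the replicate number as a block (536), which removes the variation shared by same-numbered arrays. Leaving out 1 array gave 2 to 3 genes. EGFL7 changed by 1.34 to 1.67 when 1 array was left out, losing its call without any 1 control array or antisense replicate 3. It changed by 1.47 without a call when all clusters above the 25th percentile were tested, the cause of which was not tested.

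The paired count of 536 became 156 with no filter on dim probes, 826 with the filter at the 50th percentile and 991 with a trended and robust prior. It was 904 with both no filter and that prior, and 1 with all clusters above the 25th percentile. With a change of at least 1.5-fold it was 109, at a limma adjusted p under 0.10 it was 997, and without 1 replicate number 57 to 489. It was 493 to 632 under the other scalings, weights and cluster rule. Dropping a replicate number leaves fewer arrays, and the looser and stricter thresholds act by construction; for the others the cause was not tested. The count of 11 lists became 0 with an estimated correlation and 1 with fry, and the paired count of 13 likewise became 0 and 1. It was 11 to 14 otherwise. Fry asks another question, and the estimated form allows for correlation between members. Over the 11 lists such correlation was estimated at −0.011 to 0.944 without pairing. The highest values were 0.944 for G2/M genes, 0.820 for replication histones and 0.677 for G1/S genes, far above the preset 0.01. How much of the loss it accounts for in these lists was not tested. It cannot account for the loss in targets named in other studies, the list with the estimate of −0.011. Their unadjusted camera p still went from 0.00531 to 0.0340. Of the 4 targets taken up by the study, 2 rose in the paired fit with the filter at the 50th percentile or with the trended and robust prior, and 1 rose with median centring. By camera, the pairing changed the call of the NF-kB and the TGF-beta and BMP lists and of no other list; by fry it ended the call of targets named in other studies and gave that of the TGF-beta and BMP list. Without pairing, the NF-kB list also passed by camera with the filter at the 50th percentile (adjusted p = 0.0290) or array weights (0.0245), and the TGF-beta and BMP list with that filter (0.0142), quantile normalization (0.0433), median centring (0.0491) or array weights (0.0200).

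Among values with no call, the following changed direction, and the cause was not tested. With 1 array left out, CD14 ranged from −0.018 to 0.195, EPB42 from −0.27 to 0.0022, HBB from −0.049 to 0.42, RGS3 from −0.084 to 0.056 and VCAM1 from −0.27 to 0.149. List medians ranged from −0.0021 to 0.094 for tip cell genes, −0.090 to 0.090 for interferon genes, −0.037 to 0.012 for the unfolded protein response, −0.024 to 0.109 for sterol synthesis, −0.019 to 0.053 for junction genes, −0.032 to 0.085 for leukocyte markers, −0.050 to 0.035 for fibroblast and smooth muscle markers and −0.172 to 0.028 for red cell markers. The median also changed sign for interferon genes with array weights (−0.012) and for junction genes with median centring (0.0063). The direction of the set test turned for tip cell genes with the replicate block (median 0.031) and without control replicate 1 (0.029) or antisense replicate 3 (0.010), for KLF genes without antisense replicate 2, where their median kept its sign (0.030 to 0.055 with 1 array left out), for fibroblast and smooth muscle markers with no filter (0.025), quantile normalization (−0.0032), median centring (0.00017), cyclic loess (−0.015), array weights (0.015) and fry (−0.018), and for red cell markers with no filter (0.0089), array weights (−0.062) and the mean of clusters (0.0089).

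With pairing, the median changed sign in at least 1 alternative for the same lists and for KLF genes (−0.0044 without replicate 1), all of them without a call in the paired fit; junction genes went to 0.033 without replicate 1 and 0.017 without replicate 2, and leukocyte markers to −0.011 without replicate 2. CD14, HBB and VCAM1 changed direction without replicate 1 and RGS3 without replicate 2.

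No other named gene changed direction. No call changed in 388 list and 1717 gene results, the latter nearly all uncalled. Calls were gained in 24 and 64 others and lost in 25 list results. Weakly expressed genes (under the 25th percentile) were not tested, and planned miR-126-3p and miR-126-5p seed searches were not run.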

Other observations

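Tests of the chromosomal neighbours, of the EGFL7 clusters, of p53 targets, of fibroblast markers and of further arterial genes were chosen only after the results they bear on were seen, as were the genes of the next paragraph, which were taken from the largest changes of the paired fit. The condition on the brightness of fibroblast markers was added after their median was seen, and the splits of the lists with pairing after those without it.

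Genes outside the fixed lists were among the largest changes. In the paired fit (limma, adjusted p under 0.05) the glycoprotein gene GPNMB fell by 1.26 on the log2 scale, the matrix gene MATN2 by 1.05, the estradiol-oxidising enzyme HSD17B2 by 0.97, and the platelet-derived growth factors PDGFD and PDGFC by 0.75 and 0.65. The Wnt modulator DKK3 fell by 0.66 on the log2 scale, the laminin-related NTN4 by 0.68 and the oxidase NOX4 by 0.57. Among genes that rose in that fit were LRRC17 (0.87), the zinc transporter SLC39A6 (0.87), MLEC (0.85), KLRG1 (0.84) and the condensin subunit NCAPG (0.73). MATN2, NTN4, NOX4 and NCAPG did not pass without replicate 1 (limma adjusted p = 0.0974, 0.0564, 0.0610 and 0.0656), and the others named here passed without each replicate number in turn.

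MIR126 and EGFL7 rose together. A rise of the whole chromosomal neighbourhood is argued against by the nearest annotated protein-coding genes, of which 17 of 20 were measured. Their median change was 0.0038 (95% bootstrap interval over genes −0.06 to 0.06), with single genes from −0.22 to 0.24, against 1.47 for EGFL7. The interval comes from resampling genes and does not measure the spread between cultures. Unprocessed primary transcript may add to the EGFL7 signal, but EGFL7 was read by 1 cluster, so transcript left unprocessed and a rise of EGFL7 mRNA cannot be told apart. More EGFL7 mRNA after a loss of mature miR-126 remains an untested alternative, and mature miR-126 was not measured.

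Mitotic genes were higher in antisense cells as a list by camera, a call lost with an estimated correlation (adjusted p = 0.467) and by fry (0.389). That 1 replicate number carries the shift is argued against by the lowest of the 3 pair medians, 0.34. An intensity-dependent bias of the normalization is argued against by the list's median, at percentile 100 of 10000 random lists matched on mean expression. A control morpholino that slowed the cycle through p53 could give the same picture, and the p53 target median of −0.086 decides nothing because the series has no untreated arm. A faster cycle after a loss of mature miR-126 is therefore a hypothesis beside an effect of either oligomer. Neither the cycle nor mature miR-126 was measured.

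Extracellular matrix genes were lower in antisense cells as a list by camera, a call lost with an estimated correlation (adjusted p = 0.467) and by fry (0.310), with 4 of 27 genes lower in the paired fit. Their median lay at percentile 0 of 10000 matched random lists, which argues against an intensity-dependent bias. Fewer fibroblasts or smooth muscle cells in the antisense cultures may contribute and cannot be told apart from a change within endothelial cells. The median of fibroblast and smooth muscle markers was −0.018 (95% bootstrap interval over genes −0.05 to 0.07), above the −0.140 of the matrix list. However, 2 of 18 markers were brighter than the 75th percentile of all clusters, too few to show a loss of these cells. A matrix programme lowered in endothelial cells by a loss of mature miR-126, itself not measured, stays untested.

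A hypothesis from GJA5 was that a wider arterial programme rose with it. Of 22 arterial genes listed without GJA5, 19 were measured, with a median of 0.19 at percentile 100 of 10000 matched random lists and pair medians of 0.10, 0.12 and 0.19. These values add no independent evidence, since the genes were listed after GJA5 and the Notch list had been seen to be higher. In the paired fit EFNB2, DLL4 and DEPP1 rose and JAG1 and EDN1 fell, 12 genes were above 0 and 7 below, and 8 of the genes also stand in the Notch list. The median of the 39 endothelial markers also lay at percentile 100, and whether a wider arterial programme rose stays open.

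Of the 10 splits of the 6 arrays into groups of 3, 1 (the real one) gave as many as 3 genes, and the highest other gave 0. Of the 4 splits that part all 3 replicate pairs, 1 gave as many as 536 genes in the paired fit, and the highest other gave 0. For the lists, 4 of the 10 splits gave at least the real 11, the highest other being 14 for a split that keeps the arrays numbered 2 together and those numbered 3 together, and in the paired fit 1 of 4 gave at least the real 13, the highest other being 9. The splits are too few for a share under 0.05. Without pairing, the real 11 lies within the range of the other splits. The number of camera calls at the preset correlation thus does not set the antisense arm apart from other differences between the arrays. The 6 splits that keep a same-numbered pair in 1 group gave 4 to 14 lists, and the 3 other splits that part all pairs gave 1 to 9.

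Clusters with no gene symbol or with several, 13837 in number, were read in separate limma fits of all 33297 clusters, with no filter on dim ones. Of them 0 passed there without or with pairing, against 976 at an unadjusted p under 0.05 without pairing. With pairing and a trended and robust prior 2 passed, but that fit called only 5 of all clusters. These counts therefore cannot be set against the 536 genes of the filtered paired fit. They do not show that such clusters were unchanged. Ribosomal protein genes had a median at percentile 0.01 of random lists matched on mean expression. Every list compared in this way lay at percentile 0.01 or lower or at 99.79 or higher. The percentile thus does not set the ribosomal protein genes apart from the other lists compared.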
